A study of Homo sapiens with 20 samples.

How the data were processed

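RNA from 5 lines of the WM793 melanoma cell line was hybridised to Affymetrix Human Exon 1.0 ST arrays, 4 per line, and 1 table of all 20 arrays was analysed. Its values are log2 expression values per transcript cluster, normalized with RMA in R by the authors per the labels and the design text. The log2 scale was read from the range of the deposited values. RMA and limma are named in the submitters' processing notes; their versions, the annotation used and any filter are not given in the sources used here. RMA in general corrects background, equalises the distributions of probe signals between arrays and summarises the probes of a gene. The deposited values still differed in spread between arrays, which can widen the residual spread and lower the number of calls. Summaries over a whole cluster cannot separate a construct from the endogenous transcript, nor exons of a gene, and probes shared between gene copies give those copies linked values.

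All 18708 clusters were tested, with no filter on low values. By the platform annotation 14733 clusters carry 1 gene symbol, 2875 several and 1100 none. Of those with 1 symbol, 14705 were matched by Entrez identifier to the RefSeq gene table (assembly GRCh38.p14, used for names alone), and 0 symbols needed updating. Clusters with several symbols are given by their annotation and not as a single gene. For gene lists, 1 cluster stood for each of 14410 genes, the one with the highest mean over all arrays. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed.

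Lines and replicate numbers were taken from the sample titles. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), with 1 fit to the 5 lines and all 20 arrays, which share 1 residual spread (15 residual degrees of freedom and a prior of 4.69). A cluster was called when its Benjamini-Hochberg adjusted p over all clusters was under 0.05 and its change at least 1.5-fold. The comparisons were each NME1 line minus the parent line and wild-type minus each mutant line, 7 in all, followed by the overlap of the 4 lists against the parent line and of the 4 lists of the wild-type line. All called clusters had arrays that did not overlap between the 2 lines compared. For a cluster not selected by its values 2.86% of random splits give this. After selection by the call it is no added support. NME1 was also tested with exact permutation of its 4 against 4 arrays, for which 0.0286 is the smallest possible p.

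The 31 gene lists were fixed before the data were examined. They covered the NME family, genes reported as lower with NME1, other metastasis suppressors, melanocyte differentiation, the invasive melanoma state, cadherins, extracellular matrix, integrins, matrix proteases and motility. They also covered interferon response, class I and class II antigen presentation, inflammatory cytokines, cancer-testis antigens, mitosis, DNA replication, nucleotide excision repair, double-strand break repair, hypoxia, cholesterol synthesis, ER stress, p53 targets, nucleotide synthesis, MAPK output, TGF-beta and BMP targets and the Wnt and Notch pathways. Fibroblast, leukocyte, keratinocyte and endothelial markers stood for other cell types. Lists were tested with camera (limma, two-sided) at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 31 lists of a comparison at 0.05. Members were counted as called over all clusters and again with adjustment over the list alone.

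The rule for named genes was also fixed in advance. It took, among called clusters with 1 symbol and arrays that did not overlap, the 10 largest rises and 10 largest falls for wild-type minus parent, the 5 and 5 largest for each other comparison, the same 10 and 10 for the 2 overlaps, the NME genes, and up to 4 called members of a list. Names outside it are said to be so.

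The procedure was tested on simulated data for wild-type minus parent with the spread of all 18708 clusters, in 10 simulations. It recovered 21.0% of clusters changed 1.5-fold, 69.3% of those changed 2-fold and 96.5% of those changed 3-fold, and called 12 of 185080 unchanged ones. For E5A minus parent, lists were drawn at random from 14410 genes and tested by camera at the preset correlation and an unadjusted p under 0.05. A list with each gene shifted by log2 0.4 was found in 10 of 10 simulations and an unshifted one in 0 of 10. Smaller shifts, such as most list medians reported below, were not simulated. Random lists cannot show how often lists of genes that vary together pass when unshifted.

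Alternatives set in advance were no fold minimum and a 2-fold minimum, quantile normalization of the deposited values, centring of each array on its median, leaving out the lowest 25% of clusters, 1 cluster per gene, array weights, an intensity trend with a robust prior, the replicate number as a block, the 2 lines of a comparison alone, lines as replicates, an estimated correlation, and leaving out each array in turn. Alternatives added after seeing the data were the side of component 2 as a block, each side alone, leaving out the 3 arrays of narrow spread, and that together with the block. Shared parent arrays were examined with 100 simulations of unchanged lines. Other splits of the arrays were counted over the 35 splits of 8 arrays, or 100 regroupings of all 20 including the real one.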

Results

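Gene expression was measured in 5 lines of WM793, an established human melanoma cell line that the labels describe as vertical growth phase. They were the parent line and 4 lines described as overexpressing NME1, either wild-type or the mutant E5A, K12Q or P96S. NME1 is a nucleoside diphosphate kinase known as a metastasis suppressor, and the series title gives the search for an expression signature of that function as its aim. Each line was run on 4 exon arrays, 20 in all, giving log2 values for 18708 transcript clusters. The design text of the series calls the 4 arrays of a line technical replicates, and each construct is represented by 1 line. The p-values below therefore measure the spread between arrays of a line, not between independent cultures or separately made lines. An empty-vector line is not among the groups analysed here.

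The arrays had medians from 6.27 on the log2 scale upward, within 0.23 of each other, and standard deviations between 1.60 and 1.99, and their number limits the precision. The first principal component held 57.2% of the variance and followed the standard deviation of the array over the 20 arrays (Pearson r = -0.994, Spearman rho = -0.976). Each had a two-sided permutation p of 1e-05, the smallest that the permutations can give, and no other relation across arrays was tested. Without the 2 arrays farthest from the median standard deviation, r was -0.987. Parent array 2, P96S array 3 and K12Q array 2 had the narrowest spreads, at 1.60, 1.67 and 1.72. The second component held 12.9% of the variance and parted 7 arrays (parent 1 and 2, wild-type 1 and 2, and array 1 of each mutant line), called side A, from the other 13, called side B. The labels give no batch that matches these sides. In each of the 7 comparisons fewer clusters had an unadjusted limma p under 0.05 (247 to 635) than the 935.4 that chance alone gives with independent clusters.

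**Figure D1:**
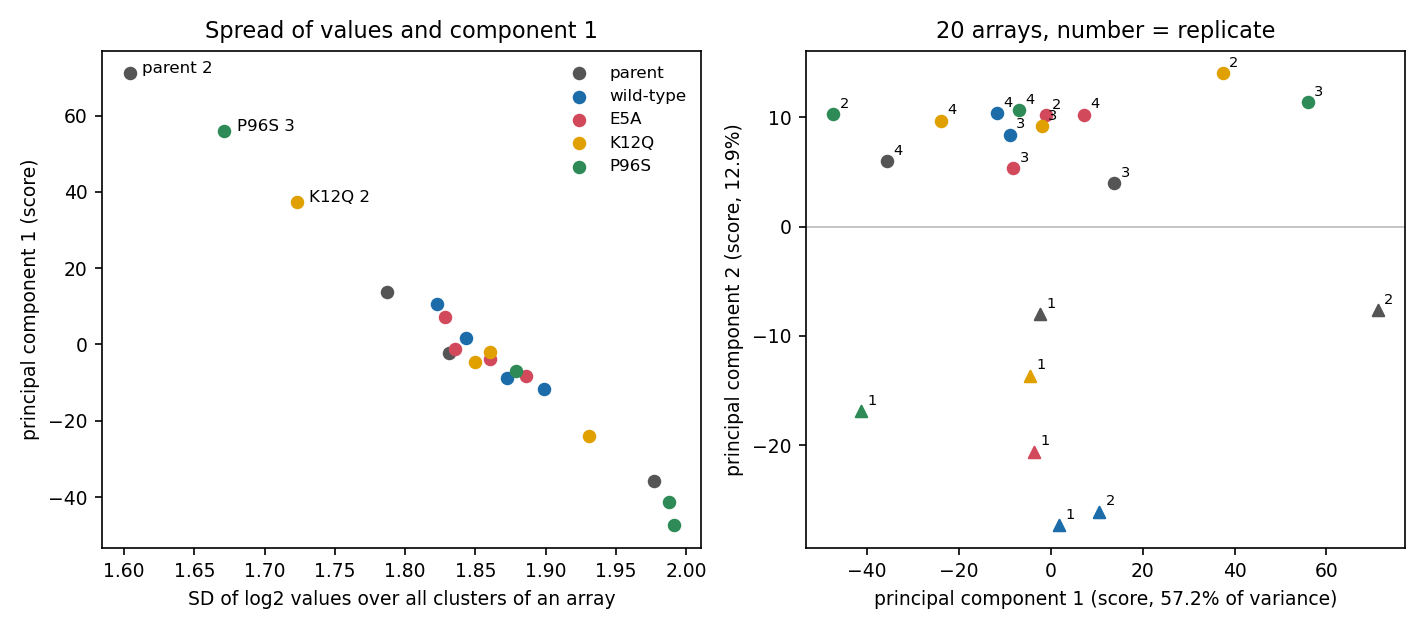
Left, score on principal component 1 against the standard deviation of the log2 values of each of the 20 arrays, coloured by line, with the 3 arrays of narrowest spread named. Right, the scores of the same arrays on components 1 and 2, with the replicate number beside each point, triangles for the 7 arrays of side A and circles for the 13 of side B; each side holds arrays of all 5 lines.

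NME1 itself was read by 1 transcript cluster, which is annotated to both NME1 and the NME1-NME2 read-through gene. Its log2 value was 9.53 ± 0.17 (SD, n = 4) in the parent line, 9.81 ± 0.05 in the wild-type line, 9.78 ± 0.11 in E5A, 9.75 ± 0.22 in K12Q and 9.78 ± 0.11 in P96S. The 4 NME1 lines thus lay between 1.17-fold and 1.22-fold above the parent line. Within sides A and B the log2 difference was 0.45 and 0.12 for wild-type, 0.31 and 0.15 for E5A, 0.065 and 0.19 for K12Q and 0.24 and 0.16 for P96S, and without the 3 narrow arrays it was 0.13 for K12Q. The two-sided exact permutation test of the 4 against 4 arrays gave p = 0.0286 for wild-type, the smallest p it allows, and 0.0857, 0.143 and 0.0571 for E5A, K12Q and P96S. The cluster was not called in any of them (limma, Benjamini-Hochberg adjusted p of 0.997, 1, 1.00 and 0.850). The 95% interval of the fold was 1.02 to 1.45 for wild-type, and the wild-type line differed from the mutant lines by log2 0.028 (E5A), 0.058 (K12Q) and 0.033 (P96S), less than the standard error of 0.12. The neighbouring cluster annotated to NME2 and the same read-through was 1.13-fold higher in the wild-type line than in the parent line and was not called. The other 6 NME genes measured were not called in any of the 7 comparisons.

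The wild-type line against the parent line asks which transcripts differ in the line given unaltered NME1, whose own NME1 cluster was not called. TRIML2, a tripartite motif family gene, rose 2.55-fold (log2 change 1.35, SE 0.13), from 6.48 ± 0.11 to 7.83 ± 0.26 (SD, n = 4 arrays each). NETO2, which encodes an auxiliary subunit of kainate receptors, rose 2.16-fold (log2 change 1.11, SE 0.12). ALDOC, the brain-type aldolase of glycolysis, rose 1.73-fold (log2 change 0.79, SE 0.13). The other 3 of the 6 called clusters, named here after their values were seen, are annotated to several copies of XAGE1, a cancer-testis antigen, and rose by log2 1.14, 1.22 and 1.33. No cluster fell. NETO2 belongs to the fixed list of 8 genes reported as lower with NME1 elsewhere, and it was its 1 called member, in the opposite direction.

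The adjusted p-values of the 3 named genes were 6.47e-05 (TRIML2), 9.7e-05 (NETO2) and 0.0298 (ALDOC), from limma with Benjamini-Hochberg adjustment over 18708 clusters, of which 18702 were not called. By camera 9 of the 31 fixed lists passed, each upward. The mitosis list led by direction, with 27 of 27 genes above the parent line (median log2 change 0.23) but none called, over all clusters or adjusted over the list alone. None of the 9 held with an estimated correlation, where adjusted p ran from 0.179 to 0.586 (0.216 for mitosis). The mitosis median was 0.096 without parent array 2, 0.10 within side B, 0.40 within side A and 0.066 without the 3 arrays of narrow spread and with side as a block; without those arrays alone the list no longer passed. The hypoxia list had a median of 0.081, which was 0.016 without wild-type array 4, where it did not pass, 0.052 without wild-type array 3, 0.033 without parent array 2, 0.12 without parent array 4 and 0.15 without wild-type array 2; after quantile normalization it was -0.011 and the list did not pass. Without parent array 2 or P96S array 3 the count of called clusters was 10 each, and ALDOC lost its call in 12 of the 20 fits without 1 array. Array weights gave 10, median centring 10, the 2 lines alone 1, sides B and A 0 and 1, and leaving out the 3 narrow arrays 11.

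**Figure D2:**
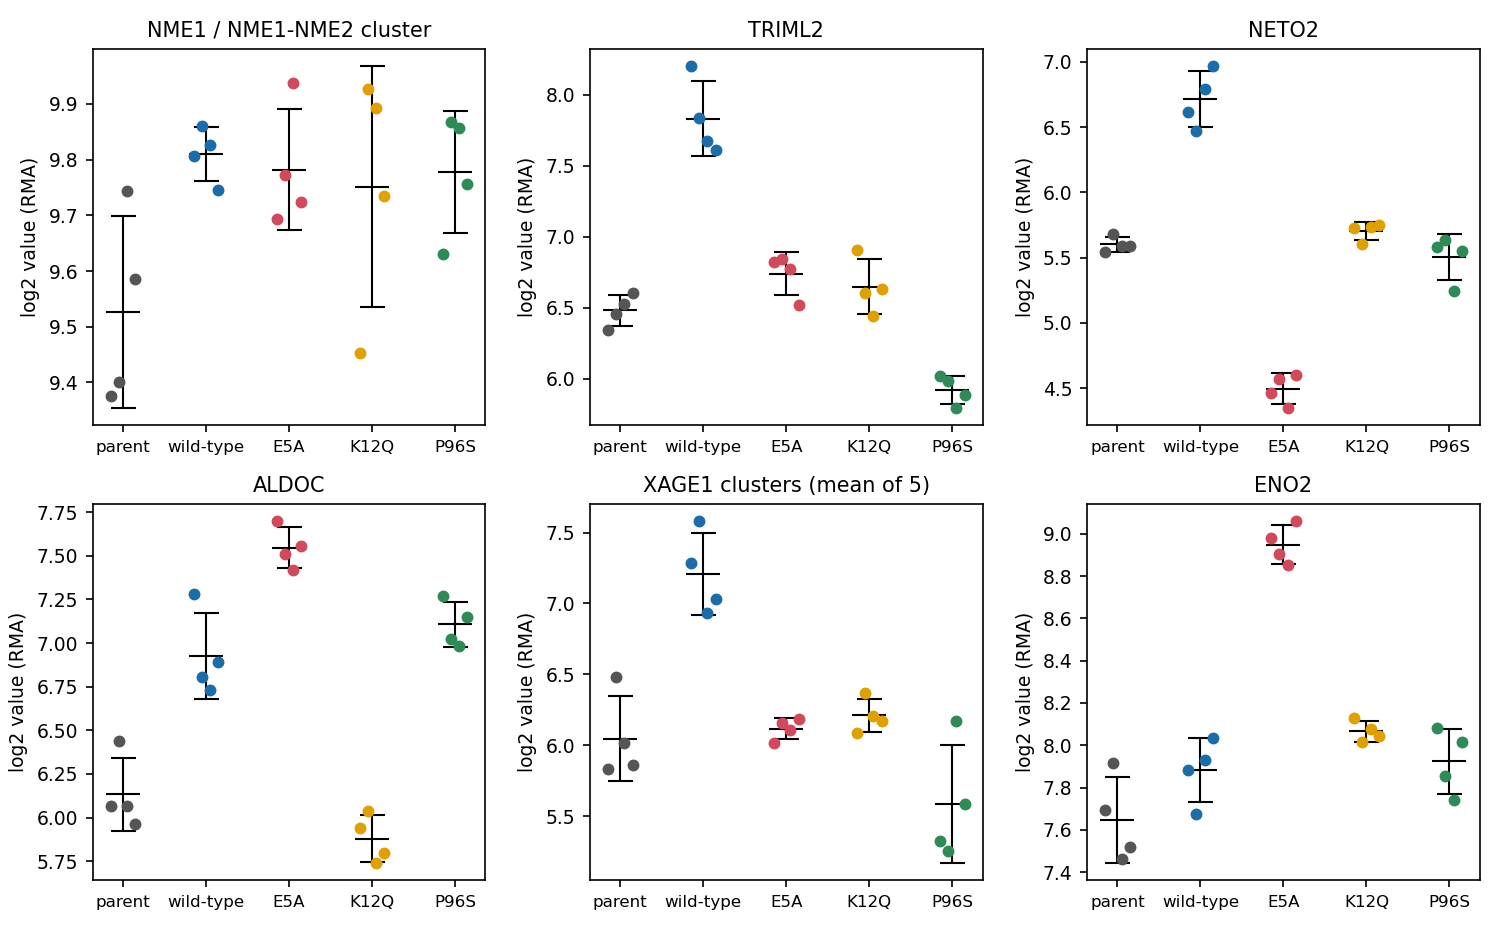
Log2 values (RMA) of 6 transcripts in the 5 lines; dots are the arrays, replicates 1 to 4 from left to right, bars the mean and SD (n = 4), and the vertical axes differ and do not start at 0. TRIML2, NETO2 and the mean of the 5 XAGE1 clusters were highest in the 4 wild-type arrays, ENO2 in the 4 E5A arrays, and NETO2 was lowest in E5A at 4.50 ± 0.12.

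The E5A line, whose substitution was made to impair the exonuclease activity of NME1, showed 26 clusters up and 14 down against the parent line. Genes of glycolysis and the response to low oxygen were higher as a group. Of the 27 measured on that list, 26 lay above the parent line with a median log2 change of 0.43, 5 rose and passed the test, 22 were not called and none fell. ALDOC rose 2.67-fold (SE of log2 0.13), ENO2 (neuronal enolase) 2.47-fold (0.12), PDK1 (pyruvate dehydrogenase kinase) 2.50-fold (0.21) and BNIP3 (a mitophagy receptor induced by hypoxia) 2.18-fold (0.16). AK4, a mitochondrial adenylate kinase, rose 2.92-fold (log2 change 1.55, SE 0.20), and NRN1, which encodes neuritin, rose 2.55-fold (1.35, SE 0.15).

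Among the genes that fell in E5A were the receptor gene VIPR1 (log2 change -1.26, SE 0.14) and NETO2 (-1.11, SE 0.12). EREG, an EGF receptor ligand, fell as well (-1.08, SE 0.17), as did SEMA6D (-0.83, SE 0.14) and IRF4, a transcription factor of the melanocyte lineage (-0.75, SE 0.12). Adjusted p (limma, Benjamini-Hochberg) lay between 1.37e-05 for ENO2 and 0.0423 for PFKFB4, the fifth called gene of the hypoxia list, named outside the rule after its values were seen. By camera 9 lists passed, and only the hypoxia list held with an estimated correlation (adjusted p = 7.57e-06; 10 members called when adjusted over the list alone). The other 8 had adjusted p from 0.0615 to 0.411 with an estimated correlation. Among them were class II antigen presentation (median log2 change 0.25, 0 of 8 called, 1 adjusted over the list alone, p 0.0615) and cholesterol synthesis (-0.19, 0 of 16 called, 0 adjusted over the list alone, p 0.0615). The class II median was 0.12 without E5A array 1, 0.66 within side A and 0.16 within side B, where that list did not pass; cholesterol synthesis did not pass without parent array 4 (median -0.19), and its median was 0.0058 within side A. With arrays centred on their medians the calls were 25 up and 7 down, SEMA6D no longer among them; SEMA6D also lost its call without E5A array 1 (log2 change -0.78). Without E5A array 3 the count was 20, without E5A array 2 or parent array 3 it was 24 each, and within sides B and A it was 6 and 1. Array weights gave 99 and the 2 lines alone 12.

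**Figure D3:**
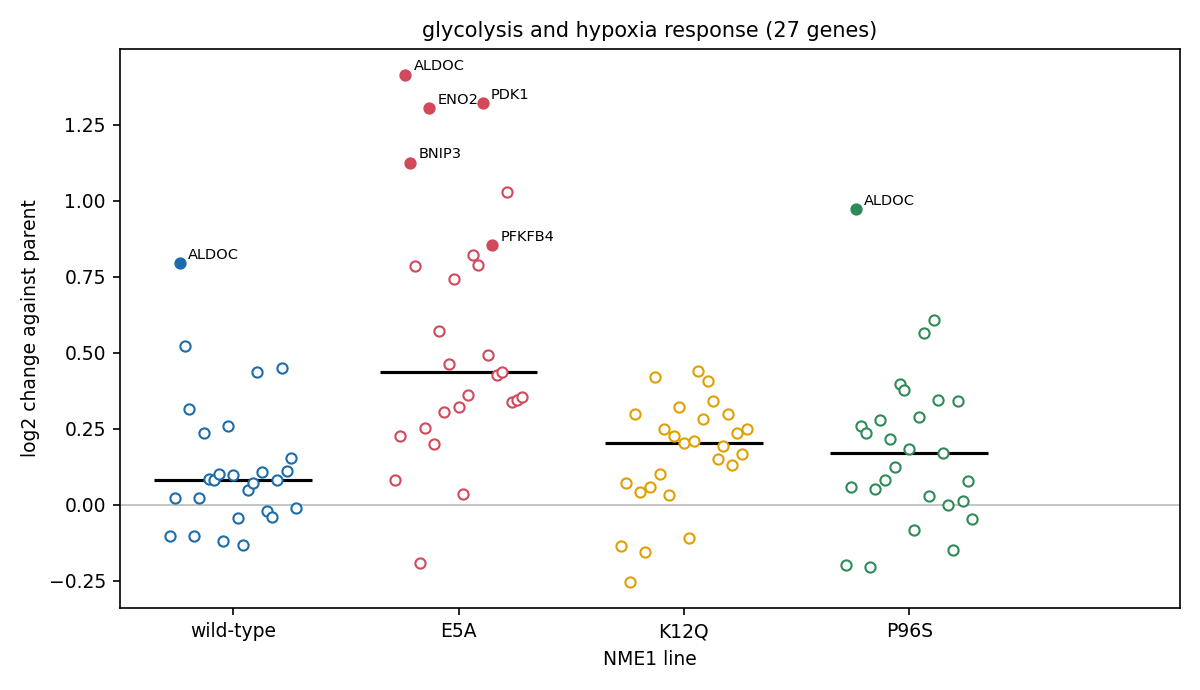
Log2 change against the parent line of each of the 27 measured genes of the glycolysis and hypoxia list (vertical axis) in the 4 NME1 lines (horizontal axis, genes in alphabetical order within a line). Filled, named points are called genes, open points are not called and black lines are medians, which were 0.081, 0.43, 0.20 and 0.17 from left to right; the first ran from 0.016 to 0.15 with 1 array left out and was -0.011 after quantile normalization.

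The K12Q line, altered at a lysine of the nucleotide-binding site, showed 1 called cluster against the parent line, with no gene symbol in the annotation (3768412, log2 change 1.05, limma adjusted p = 0.00932). At an unadjusted p under 0.05 there were 280 clusters, fewer than the 935.4 that chance alone gives with independent clusters. Of the fixed lists 11 passed, and 4 of them held with an estimated correlation: glycolysis and hypoxia (median log2 change 0.20, 23 of 27 above the parent line, adjusted p = 0.0138), matrix proteases and their inhibitors (0.066, 17 of 29, p 0.0138), MAPK pathway output (0.13, 16 of 20, p 0.0320) and, downward, fibroblast markers (-0.24, 2 of 10 above, p 0.0320). No member of these lists was called over all clusters. Adjusted over the list alone, MMP3 was called in the protease list (log2 0.80) and 0 members in each of the other 3. The other 7 lists had adjusted p from 0.0880 to 0.487 with an estimated correlation. Without parent array 2 the MAPK median was 0.019 and the list did not pass, nor did it within side A (0.11) or side B (-0.0048), whereas without all 3 narrow arrays it passed with a median of 0.033. The protease median was 0.036 without K12Q array 1 and 0.041 without parent array 3, it was 0.11 without the lowest 25% of clusters, and that list did not pass within side A. The fibroblast list passed within neither side (-0.077 in A, -0.18 in B), and the hypoxia median was 0.062 within side B.

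The single K12Q call rested on few arrays. Without parent array 2 or 3, or K12Q array 1 or 3, the count was 0, without P96S array 1 or 3 it was 2 or 3, and with side of component 2 as a block it was 2. Quantile normalization gave 1 cluster up and 1 down, and within sides B and A, or with the 2 lines alone, no cluster was called. Array weights gave 29 and leaving out the 3 narrow arrays 4.

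The P96S line carries the human counterpart of the fly Killer-of-prune substitution, and against the parent line 9 clusters were higher and 9 lower. MHC class II genes were higher as a group: of 8 measured members 3 rose, 5 were not called and none fell, with a median log2 change of 0.72. HLA-DPA1 rose 2.10-fold (log2 1.07, SE 0.18), CD74, the invariant chain, 1.94-fold (0.96, SE 0.15) and HLA-DPB1 1.90-fold (0.93, SE 0.17). A cluster annotated to both HLA-DMA and HLA-DMB was not counted in the list, as it carries several symbols. It rose 2.69-fold (log2 1.43, SE 0.16, limma adjusted p 0.000469), the largest change among the called clusters. It is named here outside the rule, after its values were seen. MMP8, a collagenase, rose 2.02-fold and ALDOC 1.96-fold. SLC7A11, the cystine transporter subunit, fell by 1.30 on the log2 scale (SE 0.22). Over the 15 alternatives other than leaving out 1 array, log2 changes ran from -1.68 to -0.69 for SLC7A11 and from 0.69 to 1.67 for HLA-DPA1.

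Interferon-response genes were lower in P96S, 33 of 36 measured having a negative change with a median of -0.22; OAS1 fell by 0.93 (SE 0.17) and 35 were not called. THY1, CPA4 and RARB, a retinoic acid receptor, fell by 0.89, 0.88 and 0.87. Genes of cholesterol synthesis were higher in 15 of 16 cases (median 0.23) and those of DNA replication in 24 of 25 (median 0.15), with no member called in either list, over all clusters or adjusted over the list alone. The hypoxia list had a median of 0.17, with ALDOC its 1 called gene, also when adjusted over the list alone. By camera 14 lists passed and these 5 held with an estimated correlation, at adjusted p of 0.000290 (class II), 0.00448 (interferon), 0.00578 (cholesterol), 0.0312 (replication) and 0.0368 (hypoxia). Adjusted over the list alone, 4 class II members were called up and 3 interferon members down. The other 9 lists had adjusted p from 0.0626 to 0.710 with an estimated correlation. Among these, fibroblast markers had a median of -0.19 (2 of 10 above the parent line, THY1 called down, 2 called down adjusted over the list alone, adjusted p 0.0626 with an estimated correlation). Leukocyte markers had -0.19 (0 of 13 above, p 0.710) and keratinocyte markers -0.15 (0 of 12 above, p 0.522), none called either way. Without P96S array 3 these 3 medians were -0.32, -0.41 and -0.30, and without parent array 2 the leukocyte and keratinocyte medians were 0.0045 and -0.018. The hypoxia median was 0.072 without parent array 2, 0.067 within side B and 0.27 within side A. Within side A the medians were also 0.47 for cholesterol synthesis, 0.46 for replication and 1.08 for class II. The interferon median was -0.33 without parent array 4, and that list did not pass within side A. The replication median was 0.23 without parent array 3, 0.26 without parent array 4 and 0.24 without the 3 narrow arrays.

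Adjusted p for the P96S genes named by the rule lay between 0.00357 (ALDOC) and 0.0336 (OAS1) by limma with Benjamini-Hochberg adjustment. The count of 18 depended strongly on the setting. Array weights gave 1648, of which 333 were up and 1315 down, and the 2 lines alone gave 0. It was 5 without P96S array 4, 6 without P96S array 2 or parent array 3, 7 without parent array 1, 9 without P96S array 1, 32 without the 3 arrays of narrow spread, and 1 and 0 within sides B and A. Of the named genes, OAS1 lost its call in 10 of the 20 fits without 1 array, HLA-DPB1 in 8, HLA-DPA1 in 6, RARB in 5, SLC7A11, MMP8 and CPA4 in 4 each and CD74 in 1, while ALDOC and THY1 lost it in none. Quantile normalization gave 10 up and 6 down, and centring on array medians 9 up and 4 down. CPA4 and RARB lost their calls under both and SLC7A11 under centring. OAS1 lost its call with the replicate block and with the intensity trend and robust prior.

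**Figure D4:**
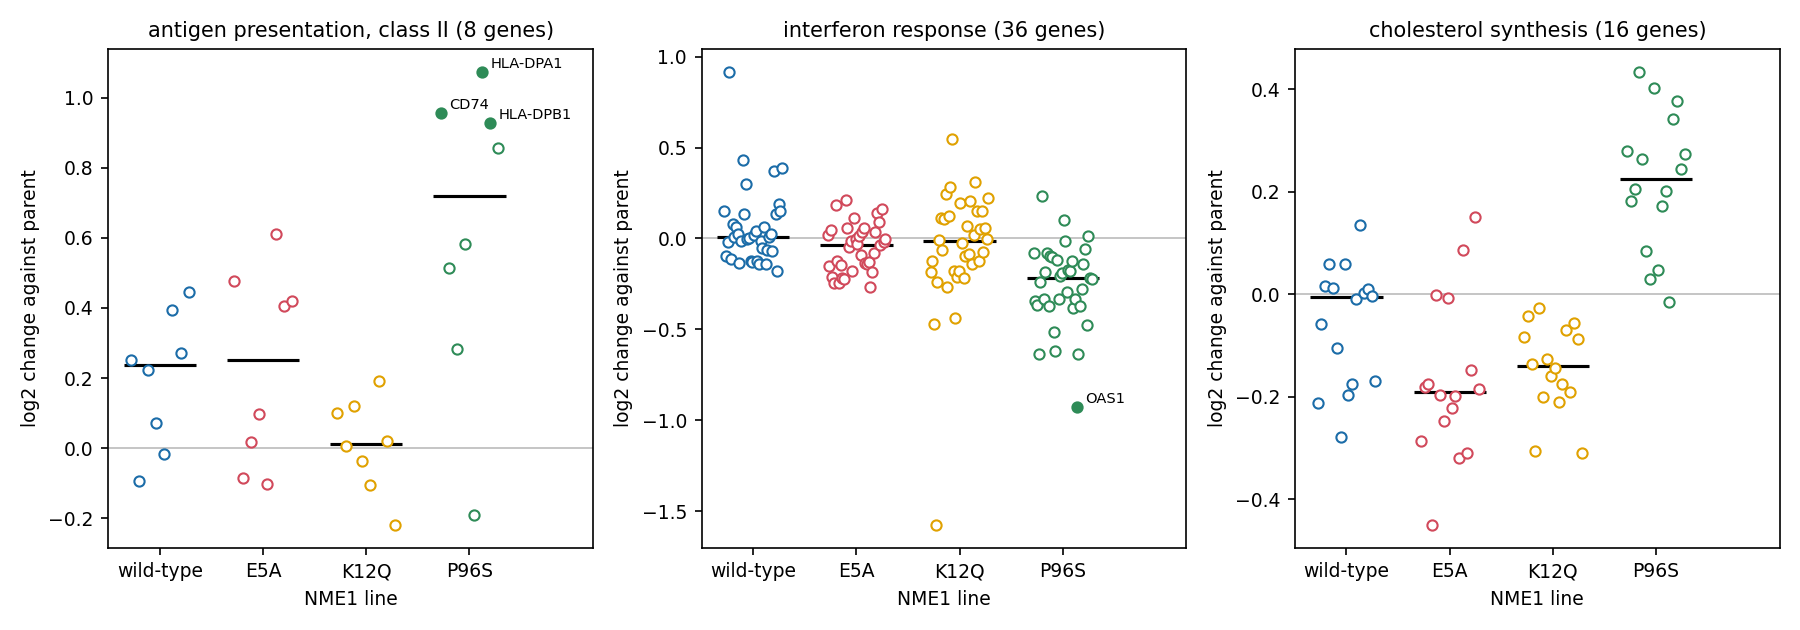
Log2 change against the parent line (vertical axes) of the measured genes of 3 fixed lists in the 4 NME1 lines, drawn as filled named points where called and open points where not, with black lines at the medians. In P96S the medians were 0.72 for class II antigen presentation, -0.22 for the interferon response and 0.23 for cholesterol synthesis.

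No cluster was called in the same direction in all 4 NME1 lines against the parent line. Simulated unchanged lines gave a mean of 0.020 clusters called in all 4, with at most 2 in a simulation. At an unadjusted limma p under 0.05, a looser level that was not simulated, 1 cluster was higher (AK4) and 5 were lower in all 4. With arrays averaged to 1 value per line, the parent line is a single value whose spread is taken from the 4 NME1 lines alone; this limma test called 0 (1618 clusters at an unadjusted p under 0.05, smallest adjusted p 0.550). ALDOC was called up against the parent line in wild-type, E5A and P96S, and its log2 value in K12Q was 5.88 ± 0.13 against 6.13 ± 0.21 in the parent line. At the preset correlation 2 lists passed upward in all 4 lines, hypoxia (medians 0.081, 0.43, 0.20 and 0.17) and nucleotide synthesis (0.12, 0.078, 0.040 and 0.087). With an estimated correlation hypoxia held in E5A, K12Q and P96S, and nucleotide synthesis in none. After quantile normalization neither list passed in wild-type. All of these comparisons share the parent arrays. Over clusters, which are not independent replicates, the log2 changes of pairs of lines correlated at r between 0.519 and 0.597, where simulated unchanged lines against the same parent arrays gave a mean of 0.417 to 0.482. With 2 parent arrays used for a line and the other 2 for its partner, r was between -0.314 and -0.149. The covariances were 0.0120 to 0.0200 against simulated means of 0.0158 to 0.0216. Each lay within the middle 95% of its simulated values, which for wild-type and E5A ran from -0.018 to 0.10. Wild-type and E5A shared 1 call in direction, ALDOC, and NETO2 was called in opposite directions. For shared calls 0.00834 were expected from independent lists, and the simulated mean was 0.030, with up to 3 in a simulation. Wild-type and P96S also shared ALDOC (0.00289 expected, simulated mean 0.020 and highest 2). E5A and P96S shared 2 calls, with 0.0192 expected and a simulated mean of 5.37, to which 1 simulation contributed 537.

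The wild-type line was next compared with each mutant line. Against E5A, 19 clusters were higher and 19 lower. NETO2 was 4.65-fold higher in wild-type (log2 2.22, SE 0.12), EREG 3.90-fold (1.96, SE 0.17), the stromelysin gene MMP3 2.38-fold (1.25, SE 0.14), TRIML2 2.13-fold and VIPR1 2.05-fold. ENO2 was lower in wild-type (log2 -1.07, SE 0.12), as were NRN1 (-1.02), HAS2, a hyaluronan synthase (-1.01), BEND5 (-0.95) and GPR146, whose change lay between those of HAS2 and BEND5. Of the 27 hypoxia genes 26 were lower in wild-type (median -0.47), 2 of them called, or 7 adjusted over the list alone, and this list alone among the 5 passing held with an estimated correlation (adjusted p = 2.49e-05). The other 4 lists had adjusted p from 0.149 to 0.207 with an estimated correlation. Adjusted p of the named genes (limma, Benjamini-Hochberg) ran from 9.56e-10 for NETO2 to 0.0205 for HAS2. HAS2 and GPR146 lost their calls in 5 and 4 of the 20 fits without 1 array, and HAS2 also after quantile normalization. Array weights gave 77. The count of 38 was 16 without E5A array 3, 22 to 24 without E5A array 1, 2 or 4 or wild-type array 2 or 3, 25 without wild-type array 1, and 5 and 0 within sides B and A.

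Against K12Q, 5 clusters were higher in wild-type and 1 lower. The interferon-induced chemokine gene CXCL11 was 5.63-fold higher (log2 2.49, SE 0.32), TRIML2 2.27-fold, ALDOC 2.07-fold and NETO2 2.01-fold, along with 1 XAGE1 cluster. NTRK3, a neurotrophin receptor gene, was lower (log2 -0.72, SE 0.11). CXCL11 varied within the wild-type line, at 7.79 and 7.68 in the arrays of side A and 6.61 and 6.43 in those of side B. Adjusted p (limma, Benjamini-Hochberg) of the 6 clusters was between 0.000454 for TRIML2 and NETO2 and 0.0107 for the XAGE1 cluster. Of the 4 lists that passed, none held with an estimated correlation (adjusted p 0.0502 to 0.625). NTRK3 lost its call in 4 of the 20 fits without 1 array and after quantile normalization. The count was 11 without parent array 2, 14 without P96S array 3, 17 without the 3 narrow arrays, 22 with array weights, and 2 and 3 within sides B and A.

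Against P96S, 24 clusters were higher in wild-type and 13 lower. TRIML2 was 3.76-fold higher (log2 1.91, SE 0.13), SLC7A11 3.41-fold (1.77, SE 0.22), EREG 3.27-fold (1.71, SE 0.17), CXCL11 2.93-fold (1.55, SE 0.32) and SPP1, encoding osteopontin, 2.44-fold (1.28, SE 0.19). TSPAN18 (-0.72), ITIH5 (-0.70), SEMA6D (-0.70), the complement gene C3 (-0.69) and the aggrecan gene ACAN (-0.69) were lower. Interferon-response genes were higher in wild-type in 34 of 36 cases (median 0.23, 3 called, 5 adjusted over the list alone). Class II genes were lower in 7 of 8 (median -0.56, 0 called, 4 adjusted over the list alone). The cluster annotated to both HLA-DMA and HLA-DMB, not counted in that list, was called lower (log2 -1.28, limma adjusted p 0.000315). Cholesterol synthesis genes were lower in 15 of 16 (median -0.28, 0 called either way). These 3 lists, TGF-beta and BMP targets (median 0.061) and fibroblast markers (median 0.12) held with an estimated correlation, at adjusted p of 0.000444, 0.000636, 0.000491, 0.0141 and 0.0314. In the last 2 lists INHBA and THY1 were the 1 called member each, and 2 and 1 were called adjusted over the list alone. The 3 remaining lists of the 8 that passed had adjusted p from 0.292 to 0.441 with an estimated correlation.

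Adjusted p for the named genes of this comparison lay between 1.54e-07 (TRIML2) and 0.0480 (CXCL11 and SEMA6D), by limma with Benjamini-Hochberg adjustment. CXCL11, SEMA6D and C3 lost their calls in 16, 18 and 14 of the 20 fits without 1 array, TSPAN18 and ITIH5 in 5 each and ACAN in 4. CXCL11 and SEMA6D also lost them after quantile normalization and after centring, and C3 after centring. Of the 15 alternatives other than leaving out 1 array, CXCL11 kept its call in 4, SEMA6D in 7 and C3 in 10. The TGF-beta list did not pass without wild-type array 3 (median 0.045), P96S array 3 (0.092) or the 3 narrow arrays, nor within side A, and its median was 0.096, 0.11 and 0.12 without wild-type array 1 and P96S arrays 1 and 2, 0.11 within side A and 0.16 within side B. The fibroblast list passed within neither side (median 0.35 in A, -0.032 in B), and its median was 0.054 without P96S array 2, and 0.20, 0.22 and 0.20 without wild-type array 4 and P96S arrays 1 and 3. The interferon list did not pass within side A. The count of 37 was 18 to 20 without wild-type array 1 or 2 or P96S array 2 or 4, 23 without wild-type array 3, 97 without the 3 narrow arrays, 144 with array weights, 11 with the 2 lines alone, and 8 and 0 within sides B and A.

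Taking the 4 comparisons of the wild-type line together, 3 clusters were higher in it than in each of the other lines and none was lower. TRIML2 was higher by at least log2 1.09 and NETO2 by at least 1.01, and the third cluster is annotated to several XAGE1 copies and was higher by 0.99 to 1.56. None of 100 simulations of unchanged lines gave such a cluster. Setting each other line apart in the same way gave 6 clusters for E5A, 4 for P96S and 0 for K12Q and the parent line. With 1 averaged value per line, the wild-type line is a single value whose spread is taken from the other 4 lines alone, and limma called 0 (784 at an unadjusted p under 0.05, smallest adjusted p 0.123). Without parent array 2 or P96S array 3 the count was 8, and within either side, with fewer arrays, it was 0. Over the 15 alternatives other than leaving out 1 array, sides included, wild-type minus parent was log2 1.08 to 1.62 for TRIML2 and 0.93 to 1.29 for NETO2.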

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

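The tests on the state of the E5A culture, on divergence between lines, on shared XAGE1 probes and on a ceiling of the signal at the level of NME1 were chosen after the results were seen. The side of component 2, within sides or as a block, and leaving out the 3 narrow arrays were settings added after seeing the data. Of 220 groups of 4 arrays examined over 44 measures, 11 held an array far from its other 3 by Dixon's criterion, and chance alone gives about 11. K12Q array 2 was far from the other K12Q arrays in NETO2 (5.60 against 5.73 to 5.75), MMP8 (8.57 against 8.93 to 8.95) and SPP1 (5.66 against 6.13 to 6.17). K12Q array 3 stood out in SEMA6D (6.45 against 6.26 to 6.29) and K12Q array 1 in TSPAN18 (6.46 against 6.77 to 6.82). E5A array 1 stood out in HLA-DPA1 (10.38 against 9.95 to 10.02), in SPP1 (5.87 against 5.41 to 5.48) and in the mean of the interferon list (6.19 against at most 6.02). P96S array 1 did so in RARB (5.50 against 5.30 to 5.33), P96S array 3 in the mean of the hypoxia list (9.12 against 9.27 to 9.29) and parent array 3 in the mean of the interferon list (6.01 against 6.13 to 6.15).

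The wild-type and mutant lines differed in the direct test of the difference, limma with Benjamini-Hochberg adjustment. There were 38 clusters against E5A, 6 against K12Q and 37 against P96S. NETO2 rose in wild-type and fell in E5A, a difference of log2 2.22.

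Genes of glycolysis and hypoxia were higher in the E5A line than in the parent line. Unequal spread between arrays was argued against, since the lower of the list's medians after quantile normalization and without the 3 narrow arrays was 0.37. The side of component 2 was argued against as the whole cause by medians of 0.40 within side A and 0.46 within side B. The side A value rests on E5A array 1 alone, set against parent arrays 1 and 2. The lowest median over the 4 NME1 lines was 0.081, in wild-type (0.016 without wild-type array 4, where the list did not pass, to 0.15 without wild-type array 2), so the list was not raised to the extent seen in E5A in each line. Whether the substitution or the state of the 1 E5A culture at harvest, such as its density or oxygen supply, could account for the rise cannot be told apart with 1 line per construct.

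TRIML2, NETO2 and 1 XAGE1 cluster were higher in the wild-type line than in each other line. All 8 contrasts of the 2 genes were called with the side of component 2 as a block, which argued against it for those with the mutant lines. For wild-type minus parent the block could not move the difference, since both lines have 2 arrays on each side. Within either side alone, with fewer arrays, neither gene kept this call. Its log2 change there was still at least 1.08 for TRIML2 and 0.93 for NETO2. Setting another line apart gave up to 6 clusters (E5A; 4 for P96S, 0 for K12Q and the parent line) against 3 for wild-type, and since E5A and P96S carry constructs of their own, divergence between separately grown lines cannot be told apart from an effect of the construct. The 5 XAGE1 clusters changed by amounts within log2 0.30 of each other, under the 0.41 of 2 standard errors, which is consistent with probes shared between copies, and they may be 1 signal. The biological explanation, the wild-type construct, stays open and untested, since the design holds 1 line with it.

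The NME1 cluster was under 1.5-fold higher in the 4 NME1 lines. A fixed limit common to all clusters at its level was argued against before any test, since cluster means in the parent line reached 13.23. The test counted 3 clusters called higher than in the parent line and adds nothing to this. BNIP3 in E5A and CD74 and HLA-DPA1 in P96S reached 10.61, 10.22 and 10.55. These means lay above the highest NME1 mean of 9.81 by over 2 standard errors. HLA-DPA1 lost its call in 6 and CD74 in 1 of the 20 fits without 1 array. All 3 started below the NME1 cluster in the parent line (9.49, 9.26 and 9.47 for BNIP3, CD74 and HLA-DPA1 against 9.53). Of the 814 clusters at or above the parent mean of the NME1 cluster, 1 (C3) was called. At that level 0 clusters changed 1.5-fold in wild-type, K12Q or P96S minus parent, and 4 did in E5A minus parent. Whether changes are damped at that level thus stays open. Saturation of the probes of NME1 itself was not analysed here. With side of component 2 as a block the mean log2 difference of the 4 lines was 0.22, still under 1.5-fold, against 0.25 without it. The block could hardly have changed this, as the wild-type difference is 0.28 with and without it by design. Within each side the log2 differences, at most 0.45, were also under 1.5-fold. Probes outside the transcribed part of the constructs could also give such a small difference; which part of NME1 the probes cover was not analysed here.

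Other splits of the arrays were counted for each comparison. Of the 35 splits of the 8 arrays, 1, the real one, gave as many clusters for wild-type minus parent (6, highest other 0), E5A minus parent (40, highest other 0), K12Q minus parent (1, highest other 0), wild-type minus E5A (38, highest other 0), wild-type minus K12Q (6, highest other 0) and wild-type minus P96S (37, highest other 1). No other split reached the real count in these 6. A split that mixes 2 lines keeps their difference inside its groups, which widens the residual spread and lowers its calls. The arrays of a line are technical replicates, so these counts cannot tell an effect of the construct from any other difference between 2 lines. For P96S minus parent 5 of the 35 splits gave as many as the real 18, so chance could not be excluded. The highest other gave 5392, and each of the 4 other splits put parent array 2 and P96S array 3, both of narrow spread, on the same side. Of the 15 other splits that keep these 2 arrays on the same side 4 reached the real count, and those that part them, as the real split does, gave at most 0. That points to a structure of the arrays, and without the 3 narrow arrays the real comparison gave 32. For the clusters called alike in all 4 NME1 lines the real count was 0, which all 100 regroupings of the 20 arrays reach by construction (100 of 100, highest other 0), so this test says nothing about chance. For the 3 clusters that set wild-type apart, 1 of 100 regroupings, the real one, gave as many (highest other 0). Regroupings mix lines too and share the limits given above.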

How the results depend on the processing

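The side of component 2, each side alone and the 3 narrow arrays were chosen as alternatives after seeing the data. Number order below is wild-type, E5A, K12Q and P96S minus parent, then wild-type minus E5A, K12Q and P96S, and "alone" is the count that sets wild-type apart. The main counts were 6, 40, 1, 18, 38, 6 and 37, with 3 alone and 0 alike in all 4 NME1 lines, and the last was 0 under every alternative. Except as given below, counts stayed within 1.5 times of these. The direction of the NME1 cluster stayed positive in every alternative in which it was repeated (0.12 to 0.45, 0.15 to 0.31, 0.065 to 0.23 and 0.16 to 0.25 for the 4 lines, and 0.23 to 0.36, 0.20 to 0.33, 0.17 to 0.32 and 0.20 to 0.32 with 1 array left out), and it was never called. Among the repeats for genes and lists, 2868 kept direction and side of the threshold, 568 lost the call and 19 reversed.

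With a 2-fold minimum E5A fell to 14, P96S to 5, wild-type minus E5A to 13 and wild-type minus P96S to 16, since fewer clusters can pass. Quantile normalization gave K12Q 2, wild-type minus K12Q 11 and alone 6. Median centring gave 10 for wild-type, 10 for wild-type minus K12Q and 7 alone. One cluster per gene gave 3 for wild-type and 0 for K12Q, as clusters with several symbols or none were left out. Array weights gave 10, 99, 29, 1648, 77, 22 and 144, and 8 alone, with 333 up and 1315 down in P96S. Side B alone gave 0, 6, 0, 1, 5, 2 and 8 with 0 alone, and side A alone 1, 1, 0, 0, 0, 3 and 0 with 0 alone, both with fewer arrays. The side as a block gave K12Q 2. Without the narrow arrays wild-type gave 11, K12Q 4, P96S 32, wild-type minus K12Q 17, wild-type minus P96S 97 and alone 9. With the block added the counts were 13, 70, 12, 48, 59, 18 and 119, and 9 alone. The 2 lines alone gave wild-type 1, E5A 12, K12Q 0, P96S 0 and wild-type minus P96S 11, with fewer residual degrees of freedom. Lines as replicates gave 0 alone. Where no reason is given, the cause was not tested.

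With the replicate block K12Q gave 2 and no other count moved by over 1.5 times. It ended the calls of OAS1 in P96S minus parent and of CXCL11 and SEMA6D in wild-type minus P96S, whose log2 changes stayed at -0.93, 1.55 and -0.70. It also ended the passes of ER stress and nucleotide synthesis in K12Q and of the genes reported as lower with NME1 in wild-type minus E5A. In their deviations from the line means, 10 of 20 arrays correlated best with an array of their own number, sought among the other lines. A random match shares the number in 1 of 4 cases. Between arrays of the same number this correlation had medians of 0.50, 0.035, 0.11 and 0.33 for numbers 1 to 4, with lowest values of 0.11, -0.85, -0.26 and -0.32. Arrays numbered 1 thus shared a structure in all 5 lines, and all of them lay on side A. For numbers 2 to 4 some pairs correlated negatively, so the numbers were not used as pairs.

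Leaving out 1 array at a time gave 4 to 10, 20 to 53, 0 to 3, 5 to 24, 16 to 44, 4 to 14 and 18 to 43 clusters, 2 to 8 alone, and 0 to 0 alike in all 4.

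Lists passing numbered 9, 9, 11, 14, 5, 4 and 8. Quantile normalization gave 3, 5, 7 and 9 against the parent line and 3 for wild-type minus E5A, and leaving out the lowest 25% of clusters gave 3 for the last. The side as a block gave wild-type minus K12Q 2. Side B alone gave 5, 4 and 3 for wild-type, E5A and K12Q and 10 for wild-type minus E5A. Side A alone gave wild-type 5, E5A 4, wild-type minus E5A 1 and wild-type minus K12Q 2. Without the narrow arrays wild-type gave 1, E5A 4 and wild-type minus E5A 2, and with the block added 3, 3 and 2. An estimated correlation gave 0, 1, 4, 5, 1, 0 and 5. Leaving out 1 array gave 4 to 13, 4 to 11, 5 to 12, 10 to 14, 2 to 10, 2 to 7 and 6 to 10.

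The 19 reversals were of list tests, and the cause was not tested. Without parent array 2 they were the invasive state and double-strand break repair in wild-type (lowest and highest medians over the arrays left out -0.014 and 0.14, -0.021 and 0.17) and double-strand break repair and nucleotide synthesis in K12Q (-0.056 and 0.17, -0.062 and 0.13). Without the narrow arrays the same wild-type lists had medians of -0.014 and -0.021, and the second -0.017 with the block added. In side B they were class I (-0.082) and class II (-0.070) in wild-type, nucleotide synthesis in E5A, K12Q and P96S (-0.085, -0.13 and -0.12), leukocyte markers in P96S (0.034), hypoxia in wild-type minus K12Q (-0.0038, where the test's direction turned and the median's did not) and double-strand break repair in wild-type minus P96S (0.023). In side A they were cholesterol synthesis in E5A and K12Q (0.0058 and 0.061), TGF-beta targets in P96S (-0.023, the test's direction alone) and mitosis in wild-type minus P96S (-0.21).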

Other observations

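Setting lines other than wild-type apart and comparing the mutant lines with each other were chosen after the results were seen. Clusters that set another single line apart from each of the other 4 are named here after their values were seen. For E5A there were 6. BEND5, NRN1, ENO2 and VLDLR, a lipoprotein receptor gene, were higher in it and VIPR1 and NETO2 lower. For P96S there were 4, among them ITIH5 (higher), SLC7A11 (lower) and 2 clusters annotated to several genes each. K12Q and the parent line had 0 each, by limma with Benjamini-Hochberg adjustment. The 280 clusters at an unadjusted p under 0.05 between these lines were fewer than the 935.4 that chance alone gives with independent clusters.

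The mutant lines also differed among themselves. E5A and K12Q differed in 32 clusters, E5A and P96S in 44 and K12Q and P96S in 53, against 6 between wild-type and K12Q. SLC7A11 had its highest log2 value in K12Q at 9.43 ± 0.19 and its lowest in P96S at 7.10 ± 0.41 (SD, n = 4). EREG ranged from 5.97 ± 0.14 in E5A to 7.94 ± 0.26 in wild-type.

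Of the 31 fixed lists, 9 passed in none of the 7 comparisons, with a lowest adjusted p (camera) of 0.0643. They were the NME family, melanocyte differentiation, cadherins, extracellular matrix, inflammatory cytokines, cancer-testis antigens, p53 targets, motility and endothelial markers, with medians between log2 -0.23 and 0.16. Clusters with several symbols were outside these tests. The NME family was thus tested on 6 genes, without the NME1 and NME2 clusters. Cancer-testis antigens were tested on 9 genes, without the called XAGE1 clusters. Also left out were called clusters annotated to SSX2 among others (log2 -0.99 and -1.05 in wild-type minus P96S), named here after their values were seen. Melanocyte differentiation genes had medians between -0.15 and 0.0030.

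Lists that passed by the preset correlation alone had small medians that moved when 1 array was left out, given here as the lowest and highest. In wild-type against the parent line they included nucleotide synthesis (0.12; 0.023 to 0.24), double-strand break repair (0.096; -0.021 to 0.17), class I antigen presentation (0.074; -0.024 to 0.23), the invasive melanoma state (0.063; -0.014 to 0.14) and the genes reported as lower with NME1 (0.11; -0.027 to 0.15), and each lowest value was without parent array 2. In E5A they included nucleotide synthesis (0.078; -0.012 without parent array 2 to 0.15), integrins (0.052; 0.031 to 0.22 without parent array 4) and other metastasis suppressors (0.041; 0.014 without parent array 1 to 0.11 without parent array 2). In K12Q they included double-strand break repair (0.092; -0.056 to 0.17), nucleotide synthesis (0.040; -0.062 to 0.13), both lowest without parent array 2, and ER stress (0.014; -0.029 without K12Q array 1 to 0.054 without parent array 2). In P96S they included double-strand break repair (0.20; 0.077 to 0.29) and nucleotide synthesis (0.087; 0.022 to 0.20), both lowest without parent array 2, nucleotide excision repair (0.10; 0.040 without P96S array 1 to 0.14) and the Wnt and Notch pathways (-0.11; -0.19 without P96S array 3 to -0.037 without P96S array 1).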
